A study of Mus musculus with 14 samples.

How the data were processed

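RNA was purified with RNeasy columns from sorted CD4 T cells of splenocytes, converted to biotin-labelled cRNA, hybridised to Illumina mouse BeadChips and read on an iScan scanner, per the labels' protocols. The scan software and its settings are not given in the sources used here, nor is the chip on which each array lay. The deposited table of non-normalized intensity values, so named per the file headers, holds a signal for each of 45281 probes on the 14 arrays on a linear scale, from 25.8 to 48424.2. Its detection columns, deposited as a fraction between 0 and 1, rise with the signal on every array (rank correlation 0.98 to 0.99), so they were read as 1 minus the detection p-value. The deposited series matrix holds log2 values with a median of 5.69 on each array (5.691 to 5.694). Its scale, centring and direction were settled from the values: quantile normalization of the raw signal followed by log2 gave the matrix with a largest difference of 0.0000. No column of another series was used (0 columns).

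Gene symbols came from the platform annotation given with the series, in which 34885 probes carry 1 symbol, 18 several and 10378 none. Symbols can be old, and probes with several or none were not named. Groups and replicate numbers were taken from the sample labels. The series' design text names PSGL1hi Ly6Clo cells for more than 1 of the 5 populations, so it was not used for grouping. No pair of arrays was counted as 1 sample: correlations within groups ran from 0.9755 to 0.9975.

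Signals were background-corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with background moments inferred from the detection p-values, offset 16, quantile normalization, log2). Probes with a detection p below 0.05 on at least 2 arrays were kept (21136), and for each symbol the probe with the highest mean over all arrays stood for the gene, which left 10846 genes, 4349 of them with more than 1 such probe. A model with 1 mean per group was fitted to all 14 arrays with lmFit and eBayes (9 residual degrees of freedom), so that the 5 groups share 1 estimate of the spread. The 9 comparisons are contrasts of that fit, with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes of a comparison, and a gene was called at an adjusted p below 0.05. Errors of log2 differences are standard errors of the fit, and fold changes are powers of the base of the log2 difference. The number of arrays limits the precision, the more so for the PSGL1lo group with 2.

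A gene whose probe was detected on no array of the dimmer group has only a bound there. Its change is given as "at least N-fold", from the bright group's mean over the dim group's mean of, per array, the higher of the probe's own value and the lowest normalized value of a detected probe (4.81 to 5.18 on the log2 scale). List medians were also computed with such genes at their bounds, and with 0 where neither group had the gene, and are printed beside the median of a called list that this moved by more than 0.1.

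The 17 gene lists were Th1 effector, Tfh, naive and lymph-node homing, survival and common gamma chain receptor, cell cycle, inhibitory receptor, T cell receptor early response, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol synthesis, migration and adhesion, and other helper lineage genes, markers of B cells, myeloid cells and NK and CD8 T cells, and heat shock and stress genes. A list of red cell markers had fewer than 5 measured genes and was not tested. Some genes stand in more than 1 list, such as Il4 (Tfh and other helper lineage), Pou2af1 (Tfh and B cell) and Fcer1g (myeloid and NK). Lists were tested with camera at a preset gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, with an estimated correlation and fry as alternatives (statmod 1.5.0). Positions between groups were computed by projecting each array onto the line between 2 group means over the genes called between them.

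The named genes follow a fixed rule. For each of the 6 main comparisons it takes the 5 largest rises and 5 largest falls among called genes with non-overlapping groups, leaving out clone and predicted names, and up to 4 called members of each list with the largest change. It always takes Selplg, Ly6c1, Ly6c2, Tbx21, Ifng, Gzmb, Bcl6, Cxcr5, Il21, Il7r, Bcl2, Ccr7, Tcf7 and Mki67, and 1 further gene that is not reported here. Of the genes listed, Ly6c2, Tcf7 and Mki67 had no probe with the symbol here and Gzmb lay below the detection filter. The text leaves out some genes of smaller change. Groups, comparisons, the tests of genes and lists, the naming rule and the alternatives were fixed before the data were examined. Some further genes, and some tests of explanations, were chosen later and are named as such. Where a named gene had further detected probes (213 gene and comparison pairs), 21 had 1 or more of the opposite sign. Signals of near-identical genes (Ly6c1 and Ly6c2, Lyz1 and Lyz2, the Klra family, Trbv13-1 and Trbv13-2) cannot be parted with certainty.

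The procedure was tested on simulated data drawn on the 10846 genes with 200 genes changed by known amounts. For Ly6Chi against Ly6Clo cells 10.4%, 86.6% and 100.0% of genes changed by 0.5, 1 and 2 on the log2 scale were called, with 4 unchanged genes among 135 calls. For Ly6Chi against PSGL1lo cells the shares were 7.5%, 74.6% and 100.0% (8 unchanged of 129 calls), and for memory against naive cells 13.4%, 79.1% and 100.0% (12 of 140). In simulations of the same 3 comparisons camera recovered a shifted list (adjusted p = 1.41e-21, 1.67e-16 and 3.95e-20) with 0 of 16 unshifted lists called. The noise was drawn independently for each gene and alike for all arrays. These runs therefore do not show how often lists of correlated genes are called wrongly. On 1 axis, from Ly6Clo to Ly6Chi cells, a position of 0.3 was returned as 0.321 ± 0.008.

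The alternatives were log2 and quantile normalization with no background correction, normexp with an offset of 50, cyclic loess, the series matrix, no detection filter, a strict filter (detection p below 0.01 on all arrays of a group), all probes, replicate number as a block, a fit of the 2 groups alone, an intensity trend, array weights, a minimum change of 1.5-fold and leaving out each array in turn. A BeadChip block was not run. Probes without a symbol were left out of the comparisons. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.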

Results

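Gene expression was measured on Illumina mouse BeadChips in CD4 T cells from Smarta mice, a transgenic strain whose T cell receptor recognises a peptide of lymphocytic choriomeningitis virus (LCMV). The 14 arrays fall into 5 groups. Naive cells gave 3 arrays. Cells of day 8 after infection were sorted on PSGL1, a selectin ligand encoded by Selplg, and on the surface antigen Ly6C, and gave 3 arrays of PSGL1hi Ly6Chi cells, 3 of PSGL1hi Ly6Clo cells and 2 of PSGL1lo Ly6Clo cells. Memory cells of day 60, sorted as PSGL1hi, gave 3 arrays. The series title speaks of T helper 1 (Th1) and T follicular helper (Tfh) cells. Th1 cells make interferon gamma, and Tfh cells help B cells in follicles. The labels do not say which sorted population stands for which. Mean raw signal per array lay between 355.7 and 570.5, except for the first PSGL1lo replicate at 138.9, and 34.9% to 41.4% of probes were detected per array. After filtering, 10846 genes were tested. The labels call the arrays of a group independent samples without naming the animals, so p-values measure the spread between those samples. Fold changes are followed by the adjusted p of limma, and levels are normalized log2 intensities given as mean ± SD.

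**Figure D1:**
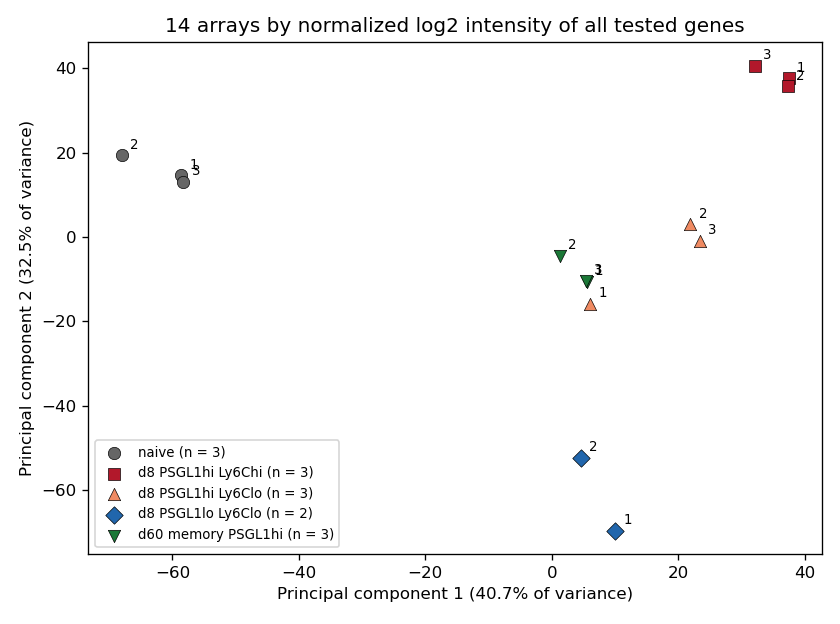
First and second principal components (40.7% and 32.5% of the variance, arbitrary units of log2 intensity) of 10846 genes on the 14 arrays, with 1 point per array, coloured by group and numbered by replicate. Ly6Clo replicate 1 lies beside the 3 memory arrays, apart from Ly6Clo replicates 2 and 3.

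The 2 genes behind the sort followed the labels in direction, but each also differed between populations that share a label. Selplg was 8.81-fold higher in Ly6Chi cells than in PSGL1lo cells (14.12 ± 0.15, n = 3, against 10.98 ± 0.15, n = 2, adjusted p = 8.80e-09). It was 4.86-fold higher in PSGL1hi Ly6Clo cells (13.26 ± 0.13, n = 3) than in PSGL1lo cells (adjusted p = 8.23e-07). Between the populations labelled PSGL1hi, Selplg was called higher in Ly6Chi cells, by 0.86 on the log2 scale, with its other probe at 1.23. Ly6c1, which encodes a form of Ly6C, was at 13.40 ± 0.17 in Ly6Chi cells, at 6.98 ± 0.96 in PSGL1hi Ly6Clo cells and undetected in PSGL1lo cells (4.38 ± 0.11). Memory cells held an intermediate Ly6c1 level of 10.49 ± 0.62. Ly6c1 and its near-identical neighbour Ly6c2 may share a probe's signal, and no probe with the symbol Ly6c2 was used here.

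The first comparison asked what separates the Ly6Chi (n = 3) from the Ly6Clo (n = 3) cells among PSGL1hi cells of day 8. In none of the comparisons below can gene changes be parted from a difference in the make-up of the sorted cells. Foxp3 and Trbv13-1, for example, differed between Ly6Chi cells and each of Ly6Clo, PSGL1lo and memory cells. Ly6c1 was 85.4-fold higher in Ly6Chi cells (log2 difference 6.42 ± 0.37 SE, adjusted p = 4.99e-08). It was followed by Fcgr2b, the inhibitory receptor for IgG (11.3-fold, adjusted p = 6.76e-06), Cx3cr1, the fractalkine receptor (8.41-fold, adjusted p = 1.60e-05), the integrin chain gene Itgad (8.07-fold, adjusted p = 2.74e-06) and Nccrp1 (7.55-fold, adjusted p = 1.85e-04). Without Ly6Clo replicate 1 Fcgr2b was 7.47-fold and Nccrp1 4.87-fold higher. Foxp3, the lineage factor of regulatory T cells, was 37.8-fold lower in Ly6Chi cells (6.02 ± 0.22 against 11.26 ± 0.43, adjusted p = 4.06e-09). Gpr83, a receptor abundant in regulatory T cells, was 29.1-fold lower (adjusted p = 4.43e-08) and Nrn1 was 28.8-fold lower (adjusted p = 1.55e-07). Ncmap and Actg2 were undetected in Ly6Chi cells and at least 18.2-fold and at least 14-fold lower there (adjusted p = 4.43e-08 and 3.24e-07). Of 3 further Foxp3 probes, 1 had the opposite sign (log2 difference 0.44), and the other Gpr83 probe differed by -0.29.

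Th1 effector genes were higher in Ly6Chi cells, with 20 of 29 measured genes risen and 1 fallen (22 and 1 adjusted over the list alone, median log2 difference 1.23, adjusted p = 1.82e-15). S1pr5, a sphingosine phosphate receptor that directs cells out of tissue, rose 5.07-fold (adjusted p = 1.93e-05), the chemokine receptor gene Ccr2 rose 4.2-fold (adjusted p = 4.19e-07) and Klrd1, which encodes the lectin receptor CD94, rose 4.18-fold (adjusted p = 3.87e-05). Tbx21, the Th1 transcription factor, rose 2.67-fold (11.78 ± 0.03 against 10.37 ± 0.36, adjusted p = 1.67e-04). Ifng, which encodes interferon gamma, rose 2.91-fold (12.20 ± 0.08 against 10.66 ± 1.04, adjusted p = 0.0061), or 1.92-fold without Ly6Clo replicate 1. The member that fell, Prdm1, was chosen after its values were seen (log2 difference -0.49, adjusted p = 0.033).

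Tfh genes were lower in Ly6Chi cells: 15 of 28 fell and 1 rose (15 and 2 adjusted over the list alone, median log2 difference -0.81, adjusted p = 1.96e-08). Izumo1r, the folate receptor 4 gene, was 14.4-fold lower (adjusted p = 4.81e-08), the interleukin 6 receptor gene Il6ra 7.84-fold lower (adjusted p = 9.65e-06), and Il4 undetected in Ly6Chi cells and at least 9.28-fold lower (adjusted p = 1.78e-08). Cxcr5, the receptor that draws T cells to follicles, was 4.28-fold lower (8.77 ± 0.21 against 10.87 ± 0.21, adjusted p = 1.08e-04), and Bcl6, the Tfh transcription factor, was 1.87-fold lower (9.29 ± 0.16 against 10.19 ± 0.03, adjusted p = 3.09e-04). Il21 fell by 1.23 on the log2 scale (adjusted p = 0.0342), a call that ended without Ly6Chi replicate 2 (0.0569) or 3 (0.165) or Ly6Clo replicate 3 (0.128). The member that rose, Cd40lg (log2 difference 0.67, adjusted p = 0.0143), was chosen after its values were seen.

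Naive and lymph-node homing genes were also lower in Ly6Chi cells, with 12 of 20 fallen and 0 risen (13 and 0 adjusted over the list alone, median log2 difference -0.90, adjusted p = 4.31e-09). Igfbp4 was 6.11-fold lower (adjusted p = 1.62e-04), or 9.22-fold without Ly6Clo replicate 3. Ccr7, the lymph node homing receptor gene, was 4.38-fold lower (adjusted p = 1.35e-06) and Id3 4.32-fold lower (adjusted p = 7.95e-05). Il7r, the interleukin 7 receptor gene, was 2.93-fold lower (10.61 ± 0.14 against 12.16 ± 0.38, adjusted p = 4.23e-05). Cell cycle genes rose, 10 of 35 up and 0 down (15 and 0 adjusted over the list alone, median log2 difference 0.51, adjusted p = 1.96e-08, but adjusted p = 0.317 with an estimated correlation). Prc1 and Cdk1, both active in mitosis, rose 2.14-fold and 2.04-fold (adjusted p = 9.93e-04 and 0.00462). Bcl2, which encodes a survival protein, differed by -0.17 ± 0.20 (adjusted p = 0.677).

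The list of other helper lineages, which holds regulatory, Th2 and Th17 cell genes, was lower in Ly6Chi cells: 11 of 15 fell and 1 rose (11 and 1 adjusted over the list alone, median log2 difference -1.11, adjusted p = 2.93e-10). Beyond Foxp3 and Gpr83, Ccr6, a Th17 chemokine receptor gene of that list, was 9.82-fold lower (adjusted p = 4.62e-06). Itgae, an integrin of tissue-resident and regulatory cells that stands in the migration list instead, was 17.2-fold lower (adjusted p = 2.21e-07). Trbv13-1, the segment that encodes the beta chain of the Smarta receptor and was chosen after its values were seen, moved the other way. It was at 14.58 ± 0.07 in Ly6Chi cells and 12.14 ± 1.46 in Ly6Clo cells (5.44-fold, adjusted p = 0.00402), or 3.04-fold without Ly6Clo replicate 1. Naive cells were at 10.47 ± 0.09 for Trbv13-1, which has near-identical relatives. B cell markers fell, 5 of 15 down and 2 up (9 and 2 adjusted over the list alone, median log2 difference -0.69, adjusted p = 0.0247, but adjusted p = 0.355 with an estimated correlation). Pou2af1 was 2.62-fold lower (adjusted p = 0.00354) and Cd79b 2.57-fold lower (adjusted p = 0.00317). The B cell call ended without Ly6Chi replicate 3 (0.102) or Ly6Clo replicate 2 (0.0548).

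For the remaining lists no shift was called between Ly6Chi and Ly6Clo cells. Of 32 migration genes, 15 rose and 8 fell (the same counts adjusted over the list alone, adjusted p = 0.103). NK and CD8 T cell markers had 3 of 11 up (3 up and 1 down adjusted over the list alone, adjusted p = 0.0552), with Gzmm, a granule protease gene, 4.83-fold higher (adjusted p = 2.21e-07). This list was called without Ly6Clo replicate 1 (0.0111) or Ly6Chi replicate 3 (0.019). T cell receptor response genes (2 up and 4 down of 25, 2 and 6 adjusted over the list alone, adjusted p = 0.119) were called without Ly6Clo replicate 1 (0.0111) and with no detection filter (0.0338). Interferon-stimulated genes (1 up of 35, adjusted p = 0.264) were called without Ly6Chi replicate 3 (0.0479) or Ly6Clo replicate 3 (0.0189). Inhibitory receptor genes had 3 up and 3 down of 14 (4 and 3 adjusted over the list alone, adjusted p = 0.742), with Havcr2, the TIM-3 gene, 4.64-fold higher (adjusted p = 0.00449), or 2.65-fold without Ly6Clo replicate 1. Glycolysis (adjusted p = 0.538), survival (0.826), oxidative phosphorylation (0.264), cholesterol synthesis (0.151), myeloid (0.982) and heat shock genes (0.931) were not called, and the last 2 had a median below and a mean above 0.

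In all, 1483 genes differed between Ly6Chi and Ly6Clo cells, 609 higher and 874 lower, of which 632 by at least 2-fold, and 33.2% of genes had non-overlapping groups where chance gives 10%. Without Ly6Clo replicate 1, which correlated best with a memory array (r = 0.9948, against 0.9887 for the best of its own group), 1077 genes were called.

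**Figure D2:**
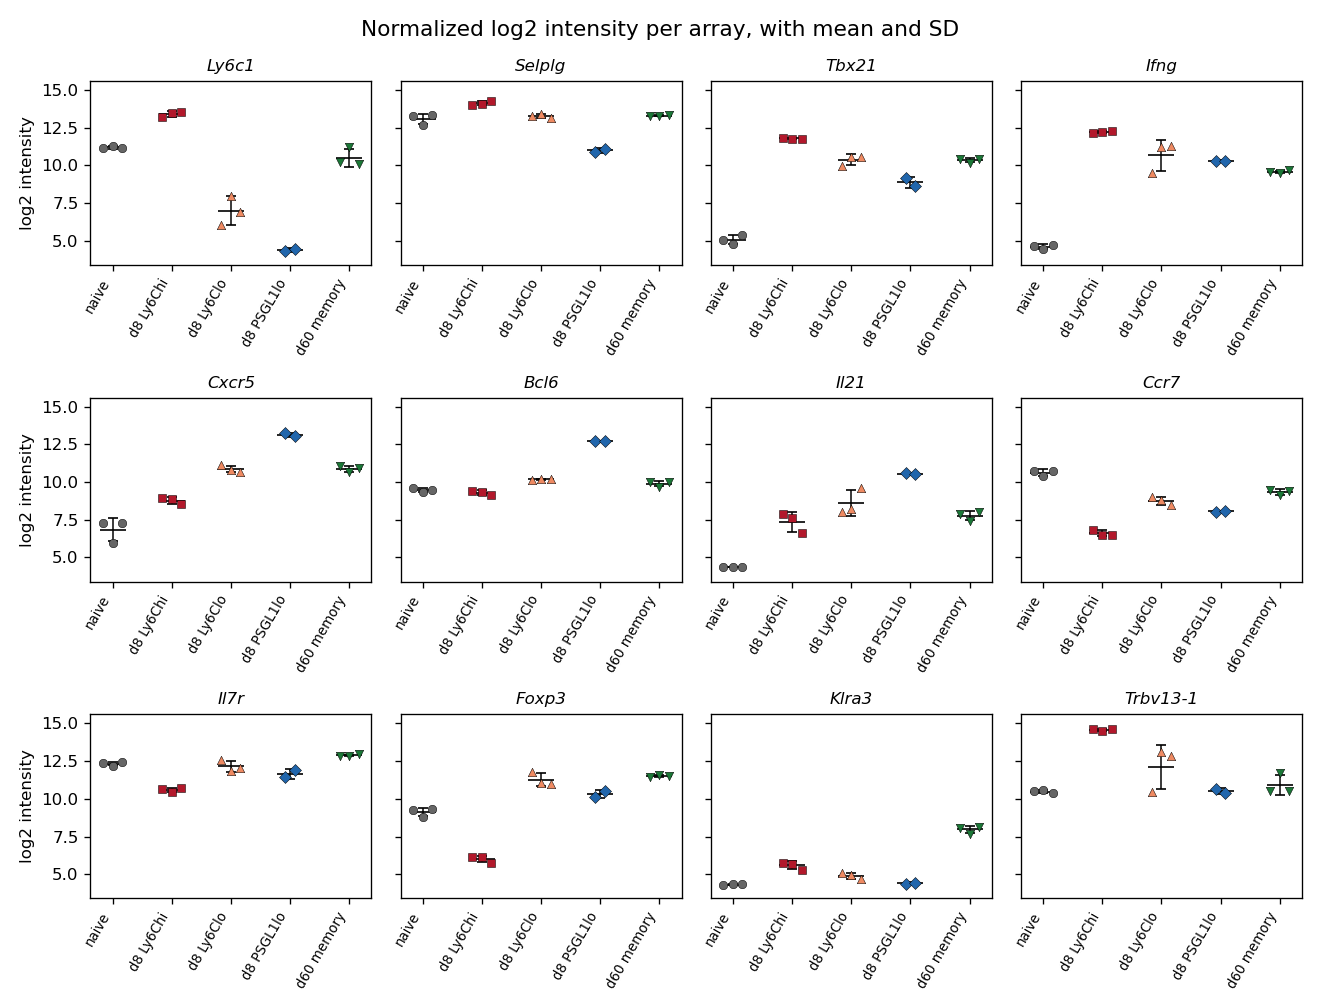
Normalized log2 intensity of 12 genes (vertical axes) on each of the 14 arrays, grouped along the horizontal axes into naive, day 8 Ly6Chi, day 8 Ly6Clo, day 8 PSGL1lo and day 60 memory cells, with group means and SD as bars. Tbx21 falls in steps from 11.78 in Ly6Chi through 10.37 in Ly6Clo cells to its PSGL1lo level, while Bcl6 and Cxcr5 are highest in PSGL1lo cells (12.71 and 13.14).

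Ly6Chi cells (n = 3) were next compared with PSGL1lo Ly6Clo cells (n = 2), the populations that differ in both sort markers. Ly6c1 was at least 349.6-fold higher in Ly6Chi cells (adjusted p = 9.23e-10). Plac8 was 147-fold higher (13.15 ± 0.11 against 5.95 ± 0.16, adjusted p = 5.74e-07) and the chemokine gene Ccl4 103-fold (adjusted p = 1.99e-06). Klrd1 was 92.8-fold higher (11.54 ± 0.11 against 5.00 ± 0.50, adjusted p = 4.08e-10) and Lgals3, the galectin 3 gene, 74.4-fold (adjusted p = 1.90e-07). Sostdc1, an antagonist of BMP and Wnt signalling, was 80.4-fold lower (6.37 ± 0.94 against 12.70 ± 0.11, adjusted p = 8.82e-09). Nrn1 was 78.2-fold lower (adjusted p = 5.42e-09), the growth factor receptor gene Igf1r 75.4-fold lower (adjusted p = 5.40e-10), and Il4 and Slc24a3 at least 58.8-fold and at least 55.4-fold lower (adjusted p = 3.82e-11 and 3.27e-10).

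Th1 effector genes rose in Ly6Chi against PSGL1lo cells, 24 of 29 up and 0 down (25 and 0 adjusted over the list alone), with a median log2 difference of 2.65, or 2.45 with undetected genes at their bounds (adjusted p = 5.0e-16). Ccl3, a further chemokine gene, rose at least 46.6-fold, Nkg7, a granule protein gene, 44.8-fold (adjusted p = 2.19e-09), Tbx21 7.51-fold (adjusted p = 1.19e-07) and Ifng 3.78-fold (adjusted p = 0.00107). Tfh genes fell, 23 of 28 down and 0 up, also adjusted over the list alone (median log2 difference -1.62, adjusted p = 3.81e-13). Cxcr5 was 20.7-fold lower (8.77 ± 0.21 against 13.14 ± 0.14, adjusted p = 5.72e-08), Bcl6 10.7-fold lower (9.29 ± 0.16 against 12.71 ± 0.03, adjusted p = 6.65e-10), Il21 9.16-fold lower (adjusted p = 2.01e-05) and Izumo1r 35.6-fold lower (adjusted p = 1.33e-09).

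Cell cycle genes were higher in Ly6Chi cells, 30 of 35 up and 0 down (32 and 0 adjusted over the list alone, median log2 difference 2.10, adjusted p = 1.52e-16, but adjusted p = 0.115 with an estimated correlation). Birc5, the survivin gene, rose 12.4-fold (adjusted p = 1.13e-07) and Prc1 11-fold (adjusted p = 1.26e-08). Interferon-stimulated genes rose, 24 of 35 up and 0 down, also over the list alone (median log2 difference 0.86, adjusted p = 1.04e-07, but adjusted p = 0.212 with an estimated correlation). Ifit3 rose 11-fold (adjusted p = 9.49e-06) and Usp18 7.53-fold (adjusted p = 1.54e-05). Among 17 cholesterol synthesis genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.00147, but adjusted p = 0.0983 with an estimated correlation), among them Sqle, squalene epoxidase (4.99-fold, adjusted p = 4.36e-07). Oxidative phosphorylation genes had 15 of 39 up and 1 down (16 and 1 adjusted over the list alone, median log2 difference 0.51, adjusted p = 0.00156, but adjusted p = 0.343 with an estimated correlation). Their largest rises, in Ndufb7 (3.09-fold, adjusted p = 4.71e-04) and Cox5a (2.64-fold, adjusted p = 4.26e-04), came to 1.93-fold and 1.79-fold without PSGL1lo replicate 1, and Ndufb7 to 4.94-fold without PSGL1lo replicate 2. The median of that list came to 0.16 without PSGL1lo replicate 1 (adjusted p = 0.0417).

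Migration genes shifted up in Ly6Chi cells, 16 of 32 up and 8 down (17 and 8 adjusted over the list alone), with a median log2 difference of 0.67, or 0.53 with undetected genes at their bounds (adjusted p = 0.00857, but adjusted p = 0.115 with an estimated correlation). Ccr2 rose at least 16.5-fold (adjusted p = 1.90e-10), Cx3cr1 24.6-fold (adjusted p = 1.91e-07) and the chemokine receptor gene Cxcr6 18-fold. Other helper lineage genes fell, 8 of 15 down and 2 up, also over the list alone (median log2 difference -0.66, adjusted p = 0.00617, but adjusted p = 0.233 with an estimated correlation). Gpr83 was 46.6-fold lower (adjusted p = 4.60e-09) and Foxp3 19.7-fold lower (adjusted p = 5.11e-09), while Il2ra, the interleukin 2 receptor alpha chain gene, rose 4.14-fold. The other Gpr83 probe differed by -0.28, and 1 of 3 further Foxp3 probes by 0.56. In the same PSGL1lo arrays Trbv13-1 was at 10.51 ± 0.18, against 14.58 ± 0.07 in Ly6Chi cells.

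Markers of other cell types differed as well between Ly6Chi and PSGL1lo cells. Myeloid markers rose, 8 of 22 up and 1 down (9 and 1 adjusted over the list alone), with a median log2 difference of 0.37, or 0.16 with undetected genes at their bounds (adjusted p = 0.017, but adjusted p = 0.233 with an estimated correlation). The shared signalling chain gene Fcer1g rose 7.26-fold (adjusted p = 4.19e-04) and the neutrophil gene S100a8 6.5-fold (adjusted p = 1.19e-04). NK and CD8 T cell markers rose, 7 of 11 up and 0 down, also over the list alone, with a median log2 difference of 1.18, or 0.92 with undetected genes at their bounds (adjusted p = 8.62e-04, but adjusted p = 0.173 with an estimated correlation). Gzmm was 5.84-fold higher (adjusted p = 3.75e-08).

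No shift was called for naive and lymph-node homing genes (2 up and 8 down of 20, 2 and 10 adjusted over the list alone, adjusted p = 0.114), although cyclic loess scaling gave 0.0347. In that list the chromatin organiser gene Satb1 rose 12.1-fold (adjusted p = 2.71e-09) and Id3 fell 10.2-fold. Inhibitory receptor genes (3 up and 6 down of 14, also over the list alone, median -0.56, mean 0.10, adjusted p = 0.492) went both ways. Havcr2 was at least 35.1-fold and Klrg1 21.7-fold higher (adjusted p = 5.40e-10 for Klrg1), and Lag3 was 7.7-fold lower (adjusted p = 2.17e-04). Il7r was 2.08-fold lower (adjusted p = 8.90e-04), Ccr7 2.75-fold lower (adjusted p = 3.20e-05), and Bcl2 differed by 0.31 ± 0.23 (adjusted p = 0.308). B cell markers had 3 up and 2 down of 15 (median 0.06, mean -0.16, adjusted p = 0.956), the 2 that fell being Pou2af1 (16.2-fold, adjusted p = 1.79e-07) and Cd22 (5.41-fold). Survival (adjusted p = 0.172), T cell receptor response (0.921, median below and mean above 0), glycolysis (0.956, median above and mean below 0) and heat shock genes (0.978) were not called. Of all genes 4038 differed, 1928 higher and 2110 lower, 1882 by at least 2-fold, and 56.2% had non-overlapping groups where chance gives 20%.

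The third day 8 comparison set PSGL1hi Ly6Clo (n = 3) against PSGL1lo Ly6Clo cells (n = 2), both sorted as Ly6Clo and parted by the sort on PSGL1. Their Ly6c1 levels still differed, as given above. Plac8 was 47.7-fold higher in PSGL1hi cells (11.53 ± 1.67 against 5.95 ± 0.16, adjusted p = 2.49e-05), Ccl4 37.1-fold (adjusted p = 7.50e-05), Lgals3 23-fold (adjusted p = 1.66e-05), Klrd1 22.2-fold (adjusted p = 7.81e-08) and the interferon-induced gene Ifitm3 21-fold (adjusted p = 9.38e-05). Without Ly6Clo replicate 1 these were 93.2-fold for Plac8, 60.6-fold for Ccl4, 38-fold for Lgals3 and 38.5-fold for Ifitm3. The vitamin D receptor gene Vdr and the G protein gene Gna14 were each 12.1-fold lower (adjusted p = 1.87e-07 and 2.96e-06), and Sostdc1 was 11.9-fold lower (9.12 ± 0.36 against 12.70 ± 0.11, adjusted p = 9.55e-06). Gal, the galanin gene, and Apoc4 were at least 10.5-fold and at least 8.46-fold lower (adjusted p = 3.00e-10 for each).

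Th1 effector genes were higher in PSGL1hi Ly6Clo than in PSGL1lo cells, 17 of 29 up and 0 down (18 and 1 adjusted over the list alone, median log2 difference 1.42, adjusted p = 7.73e-12). Il18r1, a receptor for interleukin 18, rose 20.2-fold (adjusted p = 2.66e-06), the chemokine gene Ccl5 16.8-fold (adjusted p = 5.99e-05) and Tbx21 2.81-fold (adjusted p = 2.31e-04), while Ifng differed by 0.38 ± 0.38 (adjusted p = 0.517), but by 0.98 without Ly6Clo replicate 1, where it was called (adjusted p = 3.77e-04). Tfh genes were lower, 19 of 28 down and 0 up (21 and 0 adjusted over the list alone, median log2 difference -1.18, adjusted p = 4.91e-13). Il4 was 6.34-fold lower (adjusted p = 2.31e-07), Ascl2, a Tfh transcription factor gene, 5.99-fold lower (adjusted p = 1.12e-07), Bcl6 5.71-fold lower (adjusted p = 7.81e-08), Cxcr5 4.83-fold lower (adjusted p = 1.16e-04) and Il21 3.89-fold lower (adjusted p = 0.00345). Migration genes were higher, 16 of 32 up and 5 down (19 and 5 adjusted over the list alone, median log2 difference 0.68, adjusted p = 2.26e-04). Cxcr6 rose 6.94-fold (adjusted p = 1.26e-04) and St3gal6, a sialyltransferase gene of selectin ligand synthesis, 6.38-fold (adjusted p = 1.87e-07).

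Cell cycle genes rose, 26 of 35 up and 0 down (28 and 0 adjusted over the list alone, median log2 difference 1.44, adjusted p = 7.22e-18, but adjusted p = 0.0827 with an estimated correlation). Birc5 rose 7.64-fold (adjusted p = 4.00e-06). Interferon-stimulated genes rose, 19 of 35 up and 0 down (24 and 0 adjusted over the list alone, median log2 difference 0.75, adjusted p = 6.41e-11, but adjusted p = 0.0964 with an estimated correlation). Ifit3 rose 9.73-fold (adjusted p = 5.26e-05). Cholesterol synthesis genes rose, 6 of 17 up and 0 down (7 and 0 adjusted over the list alone, adjusted p = 6.74e-04, but adjusted p = 0.0589 with an estimated correlation). Oxidative phosphorylation genes had 5 of 39 up (4 adjusted over the list alone, adjusted p = 8.25e-04, but adjusted p = 0.318 with an estimated correlation), a call that ended without PSGL1lo replicate 1 (0.0605). Survival genes had 6 of 24 up and 1 down (7 and 1 adjusted over the list alone, adjusted p = 0.0237, but adjusted p = 0.0827 with an estimated correlation), a call that ended without PSGL1lo replicate 2 (0.0594). Il2ra led with 4.85-fold (adjusted p = 8.17e-06). Naive and lymph-node homing genes had 7 of 20 up and 3 down (9 and 6 adjusted over the list alone, adjusted p = 0.0321, but adjusted p = 0.246 with an estimated correlation). Satb1 was 9.8-fold higher (adjusted p = 6.31e-08). The homing call ended without PSGL1lo replicate 2 (0.208), without Ly6Clo replicate 1 (0.0696), without background correction (0.0538) and with a normexp offset of 50 (0.067).

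Myeloid markers were higher in PSGL1hi Ly6Clo than in PSGL1lo cells, 7 of 22 up and 0 down (9 and 0 adjusted over the list alone), with a median log2 difference of 0.40, or 0.25 with undetected genes at their bounds (adjusted p = 6.22e-04, but adjusted p = 0.0942 with an estimated correlation). NK and CD8 T cell markers had 5 of 11 up and 0 down (6 and 0 adjusted over the list alone), with a median of 0.56, or 0.39 with undetected genes at their bounds (adjusted p = 0.00185, but adjusted p = 0.162 with an estimated correlation). That median was 0.85 without PSGL1lo replicate 2 and 0.91 without Ly6Clo replicate 3. Fcer1g, in both lists, rose 6.48-fold (adjusted p = 0.00168). The inhibitory receptor gene Pdcd1, which encodes PD-1, was 3.2-fold lower in PSGL1hi cells (adjusted p = 4.92e-06) and Klrg1 9.27-fold higher (adjusted p = 7.81e-08). The inhibitory list (2 up and 4 down of 14, also over the list alone, adjusted p = 0.989) had a median of 0.13 and a mean of 0.19 with a test direction of down. Ccr7 rose (log2 difference 0.67 ± 0.19, adjusted p = 0.0252), a call that ended without PSGL1lo replicate 1 (0.137), Ly6Clo replicate 1 (0.0705) or Ly6Clo replicate 2 (0.0728). Il7r differed by 0.49 ± 0.20 (adjusted p = 0.105) and Bcl2 by 0.47 ± 0.23 (adjusted p = 0.151), and each was called without 1 array, Il7r without PSGL1lo replicate 2 (0.0334) and Bcl2 without Ly6Clo replicate 1 (0.0201). Other helper lineage (5 up and 3 down of 15, 6 and 3 adjusted over the list alone, adjusted p = 0.284), B cell (4 up and 2 down, 5 and 2 adjusted over the list alone, 0.285), T cell receptor response (0.284), glycolysis (0.71) and heat shock genes (0.876) were not called.

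Between PSGL1hi Ly6Clo and PSGL1lo cells 2141 genes differed, 1046 higher and 1095 lower, 950 by at least 2-fold, and 40.8% had non-overlapping groups where chance gives 20%. That count depended on single arrays: 1035 genes were called without PSGL1lo replicate 1, 3566 without PSGL1lo replicate 2 and 1404 without Ly6Clo replicate 2.

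On an axis drawn from the PSGL1lo mean (0) to the Ly6Chi mean (1) over the 4038 genes that differed between them, PSGL1hi Ly6Clo cells lay at 0.558 ± 0.108. Memory and naive cells lay at 0.499 ± 0.022 and 0.518 ± 0.008 on this axis.

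Memory PSGL1hi cells of day 60 (n = 3) were compared with naive cells (n = 3). Past infection cannot be parted here from a difference in the make-up of the sorted cells, since markers of other cell types differed too. Erdr1 was undetected in naive cells on its brightest probe and at least 123-fold higher in memory cells (12.00 ± 0.09 against 4.49 ± 0.08, adjusted p = 1.35e-12), although a second Erdr1 probe differed by -0.48. Cxcr3, a chemokine receptor gene of Th1 cells, was 106-fold higher (12.50 ± 0.02 against 5.77 ± 1.08, adjusted p = 4.58e-09), Ccl5 71.6-fold (13.88 ± 0.04 against 7.72 ± 1.38, adjusted p = 1.44e-07). The unconventional myosin gene Myo1f was 54.3-fold and Nkg7 47.4-fold higher (adjusted p = 1.49e-10 and 8.28e-10). Without naive replicate 2 Cxcr3 was 68.9-fold and Ccl5 41.4-fold higher. Ampd1, AMP deaminase, was 20.8-fold lower (6.10 ± 0.16 against 10.48 ± 0.24, adjusted p = 7.52e-10). Tmem108 was 15.2-fold lower (adjusted p = 4.22e-09), Igfbp4 13.3-fold (adjusted p = 2.25e-06), the sodium pump gene Atp1b1 9.97-fold (adjusted p = 8.34e-07) and Pdlim4 9.19-fold (adjusted p = 3.45e-07).

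Th1 effector genes were higher in memory than in naive cells, 23 of 29 up and 0 down, also adjusted over the list alone, with a median log2 difference of 2.56, or 2.28 with undetected genes at their bounds (adjusted p = 2.15e-21). Tbx21 rose 38.2-fold (10.33 ± 0.14 against 5.07 ± 0.28, adjusted p = 1.84e-10) and Ifng at least 22.9-fold (adjusted p = 6.20e-08). Tfh genes rose, 14 of 28 up and 1 down (16 and 1 adjusted over the list alone, median log2 difference 0.63, adjusted p = 1.25e-07). Asb2 rose 31.1-fold (adjusted p = 2.15e-07), or 19.5-fold without naive replicate 2. Cxcr5 rose 16.5-fold (adjusted p = 6.20e-08), Il4 at least 12.3-fold (adjusted p = 3.32e-10) and Il21 at least 6.52-fold (adjusted p = 6.35e-06). Bcl6 differed by 0.43 ± 0.13 (adjusted p = 0.0336), a call that ended without naive replicate 2 (0.104) or 3 (0.0912) or memory replicate 1 (0.137) or 3 (0.132). Naive and lymph-node homing genes fell, 9 of 20 down and 1 up (12 and 1 adjusted over the list alone, median log2 difference -0.57, adjusted p = 7.57e-07), with Dapl1 7.85-fold lower (adjusted p = 7.33e-08) and Ccr7 2.41-fold lower (adjusted p = 6.79e-05).

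Inhibitory receptor genes were higher in memory cells, 9 of 14 up and 0 down (10 and 0 adjusted over the list alone), with a median log2 difference of 1.11, or 0.82 with undetected genes at their bounds (adjusted p = 2.09e-07). Lag3 rose 41.8-fold (adjusted p = 2.92e-07), Tigit 17-fold (adjusted p = 8.14e-09) and Ctla4 7.85-fold. Migration genes had 21 of 32 up and 2 down (22 and 3 adjusted over the list alone), with a median of 1.31, or 0.95 with undetected genes at their bounds (adjusted p = 2.76e-13), among them Itgae (27-fold, adjusted p = 1.32e-08) and Cxcr6 (at least 17.6-fold). Other helper lineage genes had 11 of 15 up and 0 down (12 and 1 adjusted over the list alone), with a median of 2.50, or 2.38 with undetected genes at their bounds (adjusted p = 1.67e-11). Ccr6 rose 32.5-fold (adjusted p = 1.99e-08), the semaphorin receptor gene Nrp1 13.4-fold (adjusted p = 2.06e-08) and Ikzf2, the Helios gene, 12.1-fold (adjusted p = 2.93e-08). Foxp3 rose 5.22-fold (11.51 ± 0.06 against 9.12 ± 0.28, adjusted p = 8.59e-07), and 1 of 3 further Foxp3 probes differed by -1.74. In the same arrays Trbv13-1 was at 10.92 ± 0.68 in memory and 10.47 ± 0.09 in naive cells.

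Markers of other cell types were higher on the memory arrays than on the naive arrays. Myeloid markers had 12 of 22 up and 1 down, also over the list alone, with a median log2 difference of 1.01, or 0.75 with undetected genes at their bounds (adjusted p = 3.24e-06). Lyz2, a lysozyme gene of phagocytes with a near-identical copy, was at least 14.6-fold higher (adjusted p = 6.20e-08) and Mpeg1, a perforin-like gene of macrophages, 11.4-fold higher. NK and CD8 T cell markers had 8 of 11 up and 0 down, also over the list alone, with a median of 1.96, or 1.77 with undetected genes at their bounds (adjusted p = 5.61e-08). Klra3, of the near-identical Ly49 receptor family, was at least 7.56-fold higher (adjusted p = 8.28e-10). B cell markers had 8 of 15 up and 0 down (10 and 0 adjusted over the list alone, median 0.78, adjusted p = 1.78e-04, but adjusted p = 0.0841 with an estimated correlation). Cd22 rose at least 6.08-fold (adjusted p = 1.09e-09). The invariant chain gene Cd74 was 4.73-fold higher (adjusted p = 0.00698), or 2.44-fold without naive replicate 2.

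Cell cycle genes were also higher in memory than in naive cells, 24 of 35 up and 1 down (27 and 1 adjusted over the list alone, median log2 difference 1.11, adjusted p = 1.23e-12, but adjusted p = 0.0841 with an estimated correlation), with Tk1, thymidine kinase, at 7.91-fold (adjusted p = 7.17e-07). Survival genes had 7 of 24 up and 1 down (8 and 1 adjusted over the list alone, adjusted p = 0.0498, but adjusted p = 0.0841 with an estimated correlation), with the interleukin 2 receptor beta chain gene Il2rb 5.88-fold higher (adjusted p = 7.58e-08). That survival call ended without background correction (0.0501), with a normexp offset of 50 (0.0518) and without naive replicate 3 (0.0628), memory replicate 1 (0.0534) or memory replicate 2 (0.0749). Oxidative phosphorylation genes were lower as a list (0 up and 1 down of 39, 0 and 0 adjusted over the list alone, median -0.22, adjusted p = 0.0185, but adjusted p = 0.407 with an estimated correlation). Il7r rose (log2 difference 0.55 ± 0.18, adjusted p = 0.0456), a call that ended without any 1 of the 6 arrays (0.0748 to 0.139). Selplg differed by 0.21 ± 0.16 (adjusted p = 0.411), Ly6c1 by -0.70 ± 0.37 (adjusted p = 0.208) and Bcl2 by -0.51 ± 0.20 (adjusted p = 0.0888). Glycolysis genes (4 up and 1 down of 17, 5 and 1 adjusted over the list alone, adjusted p = 0.0727) were called with no detection filter (0.0233) and without naive replicate 3 (0.0473). T cell receptor response genes (6 up and 1 down of 25, also over the list alone, adjusted p = 0.125) were called with no detection filter (0.0473) and without naive replicate 2 (0.0385). Interferon-stimulated (4 up and 4 down of 35, adjusted p = 0.392), cholesterol synthesis (0.247) and heat shock genes (0.384) were not called.

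In all, 2359 genes differed between memory and naive cells, 1435 higher and 924 lower, 998 by at least 2-fold, and 43.9% had non-overlapping groups where chance gives 10%.

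Memory cells (n = 3) were then set against the Ly6Chi cells of day 8 (n = 3). Foxp3 was 44.8-fold higher in memory cells (11.51 ± 0.06 against 6.02 ± 0.22, adjusted p = 2.14e-09), with 1 of 3 further probes at -0.51. Nrn1 was 43-fold higher (adjusted p = 4.09e-08), Gpr83 34.9-fold (adjusted p = 2.53e-08), Ncmap at least 20.6-fold and Actg2 at least 18.7-fold. The other Gpr83 probe differed by 0.45. The long noncoding RNA Miat was 32.2-fold lower (adjusted p = 2.05e-04), the RNA-binding protein gene Igf2bp3 19.3-fold lower (adjusted p = 2.90e-04), and Havcr2 18.3-fold lower (adjusted p = 1.81e-05). A second Miat probe differed by only -0.61, and 4 further Igf2bp3 probes by -4.25 to -0.05. The metallothionein gene Mt1 was 18-fold lower (adjusted p = 4.25e-04) and Gldc, glycine decarboxylase, 16.7-fold lower (adjusted p = 0.00201).

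Th1 effector genes were lower in memory than in Ly6Chi cells, 21 of 29 down and 0 up (22 and 0 adjusted over the list alone, median log2 difference -1.32, adjusted p = 5.19e-15). The chemokine genes Ccl3 and Ccl4 were 14.7-fold and 9.3-fold lower (adjusted p = 1.87e-04 and 0.00125), Cx3cr1 8.97-fold (adjusted p = 9.44e-06), Ifng 6.16-fold (9.58 ± 0.07 against 12.20 ± 0.08, adjusted p = 6.51e-05) and Tbx21 2.74-fold (adjusted p = 9.43e-05). Ly6c1 was 7.49-fold lower (adjusted p = 5.79e-05) and Selplg 1.79-fold lower (adjusted p = 0.00171). Naive and lymph-node homing genes were higher in memory cells, 12 of 20 up and 0 down (13 and 0 adjusted over the list alone, median log2 difference 1.19, adjusted p = 1.36e-10). Igfbp4 was 15.7-fold higher (adjusted p = 2.56e-06), Ccr7 6.71-fold (9.35 ± 0.20 against 6.60 ± 0.20, adjusted p = 1.17e-07) and Il7r 4.82-fold (12.88 ± 0.06 against 10.61 ± 0.14, adjusted p = 8.16e-07). Bcl2 differed by 0.21 ± 0.20 (adjusted p = 0.55).

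Tfh genes were higher in memory than in Ly6Chi cells, 12 of 28 up and 1 down (14 and 2 adjusted over the list alone, median log2 difference 0.53, adjusted p = 4.27e-05, but adjusted p = 0.0832 with an estimated correlation). Izumo1r rose 16.7-fold (adjusted p = 2.53e-08), Cxcr5 4.33-fold (adjusted p = 7.00e-05) and Bcl6 1.53-fold (adjusted p = 0.00421), while Il21 differed by 0.40 ± 0.36 (adjusted p = 0.516). Other helper lineage genes rose, 9 of 15 up and 1 down (11 and 1 adjusted over the list alone, median log2 difference 1.29, adjusted p = 1.61e-08, but adjusted p = 0.0532 with an estimated correlation). Itgae, which stands in the migration list instead, rose 20.2-fold (adjusted p = 1.25e-07). Trbv13-1 stood at 10.92 ± 0.68 on these memory arrays and at 14.58 ± 0.07 on the Ly6Chi arrays. Cell cycle genes fell, 23 of 35 down and 0 up (28 and 0 adjusted over the list alone, median log2 difference -0.97, adjusted p = 5.19e-15, but adjusted p = 0.128 with an estimated correlation). Prc1 was 3.06-fold (adjusted p = 2.70e-05) and Cdk1 2.97-fold lower (adjusted p = 1.11e-04). Interferon-stimulated genes fell, 10 of 35 down and 0 up (13 and 0 adjusted over the list alone, median -0.39, adjusted p = 1.40e-04, but adjusted p = 0.334 with an estimated correlation), with Usp18 2.77-fold lower (adjusted p = 0.00407).

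Among markers of other cells, NK and CD8 T cell genes had 5 of 11 up and 1 down in memory against Ly6Chi cells (6 and 1 adjusted over the list alone, median log2 difference 0.62, adjusted p = 0.0103, but adjusted p = 0.284 with an estimated correlation). Klra3 rose 5.23-fold (adjusted p = 2.07e-07) and Gzmm fell 4.99-fold (adjusted p = 1.64e-07). B cell markers (7 of 15 up and 0 down, 7 and 1 adjusted over the list alone, adjusted p = 0.0103, but adjusted p = 0.284 with an estimated correlation) were called. So were myeloid markers (9 of 22 up and 3 down, also over the list alone, adjusted p = 0.0307, but adjusted p = 0.284 with an estimated correlation). Both calls ended without Ly6Chi replicate 3 (0.0656 and 0.0673). Pou2af1 was 3.69-fold higher (adjusted p = 2.24e-04) and Lyz2 3.82-fold higher (adjusted p = 2.66e-04). Oxidative phosphorylation genes (0 up and 1 down of 39, 0 and 0 adjusted over the list alone, median -0.14, adjusted p = 0.0361, but adjusted p = 0.521 with an estimated correlation) were lower as a list. The same was called for cholesterol synthesis genes (1 up and 2 down of 17, 0 and 2 adjusted over the list alone, median -0.26, adjusted p = 0.0414, but adjusted p = 0.273 with an estimated correlation). The first call ended without memory replicate 1 (0.0569), memory replicate 3 (0.0826) or Ly6Chi replicate 1 (0.167), and the second without memory replicate 1 (0.0569), Ly6Chi replicate 1 (0.0917) or Ly6Chi replicate 2 (0.0595). Migration genes were not called (8 up and 12 down of 32, 8 and 16 adjusted over the list alone, median -0.24, mean 0.09, adjusted p = 0.232). Neither were inhibitory receptor genes (adjusted p = 0.626, median 0.16, mean -0.22), glycolysis (0.113), survival (0.718), T cell receptor response (0.873) and heat shock genes (0.79, median 0.14, mean -0.05).

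Memory and Ly6Chi cells differed in 2226 genes, 1236 higher and 990 lower in memory, 932 by at least 2-fold, and 43.1% had non-overlapping groups where chance gives 10%.

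The last of the 6 main comparisons set memory cells (n = 3) against PSGL1hi Ly6Clo cells of day 8 (n = 3) and called 22 genes, 21 higher in memory and 1 lower. Ly6c1 was 11.4-fold higher (10.49 ± 0.62 against 6.98 ± 0.96, adjusted p = 3.33e-04), Klra3 8.47-fold (7.98 ± 0.25 against 4.90 ± 0.19, adjusted p = 1.70e-07), Lyz2 8.41-fold (8.93 ± 0.42 against 5.85 ± 0.70, adjusted p = 1.83e-04) and Lyz1 8.4-fold (adjusted p = 2.40e-04). Klra7 was at least 4.04-fold higher (adjusted p = 2.61e-06) and Klre1, a further NK receptor gene, 3.36-fold (adjusted p = 0.00109). Chil3, a chitinase-like gene of macrophages (3.2-fold, adjusted p = 0.00127), and Klrk1, the NKG2D gene (2.69-fold, adjusted p = 7.63e-04), were chosen after their values were seen. Rilpl2 was the gene that fell (1.83-fold, adjusted p = 0.0477), a call that ended without memory replicate 1 (0.22), 2 (0.213) or 3 (0.0927) or Ly6Clo replicate 2 (0.271) or 3 (0.24).

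Apart from Ly6c1, the sort and lineage genes named below were not called between memory and Ly6Clo cells. Selplg differed by 0.02 ± 0.16 (adjusted p = 0.981), Tbx21 by -0.04 ± 0.20 (adjusted p = 0.974), Ifng by -1.08 ± 0.34 (adjusted p = 0.285), and Cxcr5 by 0.02 ± 0.28 (adjusted p = 0.993). Bcl6 differed by -0.29 ± 0.13 (adjusted p = 0.522) and Il21 by -0.83 ± 0.36 (adjusted p = 0.487). Il7r differed by 0.72 ± 0.18 (adjusted p = 0.186), Ccr7 by 0.62 ± 0.17 (adjusted p = 0.224), Bcl2 by 0.04 ± 0.20 (adjusted p = 0.97) and Foxp3 by 0.24 ± 0.21 (adjusted p = 0.763). Without Ly6Clo replicate 1, Ifng (-1.68, adjusted p = 1.13e-05), Il7r (0.93, adjusted p = 0.0059) and Ccr7 (0.74, adjusted p = 0.0449) were called. Trbv13-1 was at 10.92 ± 0.68 in memory and 12.14 ± 1.46 in Ly6Clo cells (2.33-fold, adjusted p = 0.451), and was called without that array (4.17-fold, adjusted p = 0.00103).

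NK and CD8 T cell markers were higher in memory than in Ly6Clo cells as a list, 3 of 11 up and 0 down (7 and 0 adjusted over the list alone, median log2 difference 0.73, adjusted p = 9.33e-13). The 6 further lists called were each lost with an estimated correlation. Naive and lymph-node homing genes (0 and 0 of 20, 3 and 0 adjusted over the list alone, median 0.26, adjusted p = 7.32e-05, but adjusted p = 0.0887 with an estimated correlation) were higher. Myeloid markers (1 and 0 of 22, 7 and 0 adjusted over the list alone, median 0.17, adjusted p = 2.37e-04, but adjusted p = 0.122 with an estimated correlation) were higher too. Cell cycle genes were lower (0 and 0 of 35, 0 and 15 adjusted over the list alone, median -0.38, adjusted p = 3.98e-12, but adjusted p = 0.195 with an estimated correlation). Interferon-stimulated genes (0 and 0 of 35, also over the list alone, median -0.25, adjusted p = 2.86e-07, but adjusted p = 0.199 with an estimated correlation) were lower, with a median of -0.45 without Ly6Clo replicate 1. T cell receptor response genes (0 and 0 of 25, 1 and 2 adjusted over the list alone, median -0.16, adjusted p = 0.00207, but adjusted p = 0.0887 with an estimated correlation) were lower. Inhibitory receptor genes (0 and 0 of 14, 0 and 1 adjusted over the list alone, median -0.20, adjusted p = 0.022, but adjusted p = 0.199 with an estimated correlation) were lower. Their call ended with no detection filter (0.209) and without memory replicate 1 (0.0521), memory replicate 3 (0.0624) or Ly6Clo replicate 3 (0.128).

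Th1 effector genes (median -0.09, adjusted p = 0.13) and Tfh genes (median -0.07, adjusted p = 0.158) were not called between memory and Ly6Clo cells. The Th1 list was called without Ly6Clo replicate 1 (7.65e-05) or memory replicate 2 (0.0362), and the Tfh list without memory replicate 2 (0.0273). Glycolysis genes (adjusted p = 0.0559) were called without Ly6Clo replicate 1 (0.007), without memory replicate 2 (0.0273), without background correction (0.0441) and with a normexp offset of 50 (0.0452). Migration genes (adjusted p = 0.0531) were called with that offset (0.0495), with no detection filter (0.0216) and without memory replicate 3 (0.0374), Ly6Clo replicate 2 (0.0477) or Ly6Clo replicate 3 (0.0347). Oxidative phosphorylation genes (adjusted p = 0.0703) were called with that offset (0.0495) and without memory replicate 2 (0.00791) or Ly6Clo replicate 3 (0.0195). Cholesterol synthesis (0.171), B cell (0.371), survival (0.589), other helper lineage (0.747) and heat shock genes (0.929) were not called.

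The count of 22 genes between memory and Ly6Clo cells depended on single arrays. It became 379 without Ly6Clo replicate 1, all 22 shared, and 13 without memory replicate 1 or 3. At an unadjusted p under 0.05 there were 1018 genes, and 16.1% had non-overlapping groups where chance gives 10%. On the axis from the Ly6Clo mean (0, replicate SD 0.172) to the Ly6Chi mean (1) over the 1483 genes that differed between them, memory cells lay at -0.065 ± 0.045. Naive cells lay at 0.080 ± 0.020 and PSGL1lo cells at -0.420 ± 0.023. The memory position was -0.099 without Ly6Clo replicate 1 and -0.016 without Ly6Clo replicate 2.

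**Figure D3:**
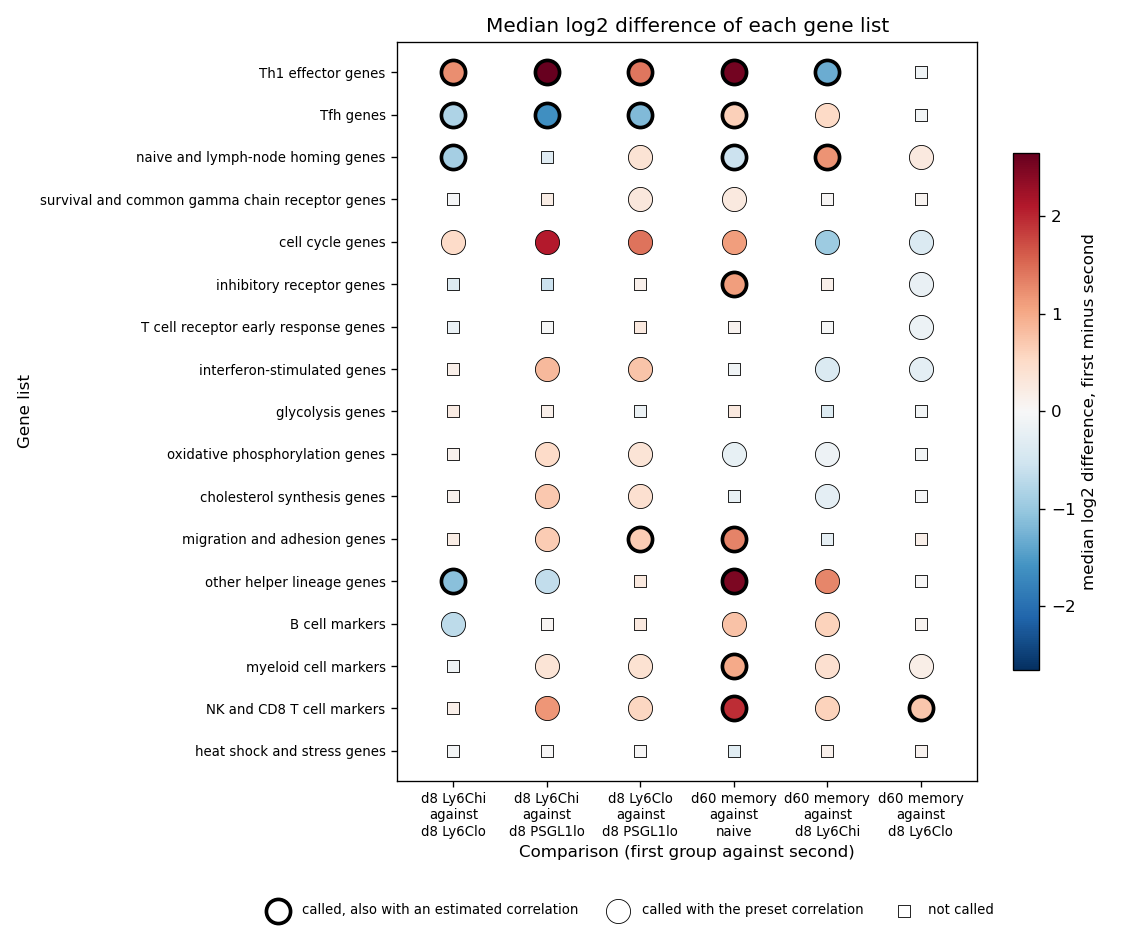
Median log2 difference (colour) of 17 gene lists (vertical axis) in the 6 main comparisons (horizontal axis). Large circles mark lists called at a preset gene correlation, thick outlines those also called at an estimated one, and small squares lists not called. Medians of Th1 effector genes were 1.23, 2.65, 1.42 and 2.56 in the comparisons where they were called higher. Between memory and Ly6Chi cells their median was -1.32.

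Against naive cells (n = 3), each day 8 population held far more Tbx21 and Ifng. Tbx21 was 104-fold higher in Ly6Chi cells (adjusted p = 9.26e-12), 39.2-fold in Ly6Clo cells (adjusted p = 1.24e-10) and 13.9-fold in PSGL1lo cells (adjusted p = 5.70e-09). Its naive level lay near the lowest values of detected probes, which makes these folds imprecise. Ifng, undetected in naive cells, was at least 141-fold, at least 48.6-fold and at least 37.4-fold higher (adjusted p = 4.41e-10, 7.45e-09 and 2.52e-08), the second at least 73.6-fold without Ly6Clo replicate 1. Cxcr5 was 3.82-fold, 16.3-fold and 78.9-fold higher (adjusted p = 5.95e-05, 5.28e-08 and 1.13e-09). Bcl6 differed by -0.18 ± 0.13 in Ly6Chi cells (adjusted p = 0.315) and rose 1.65-fold in Ly6Clo (adjusted p = 9.16e-04) and 9.4-fold in PSGL1lo cells (adjusted p = 6.93e-10). Il21, undetected in naive cells, was at least 4.93-fold, at least 11.6-fold and at least 45.1-fold higher (adjusted p = 1.20e-05, 5.69e-07 and 2.00e-08). Selplg rose 2.06-fold in Ly6Chi cells (adjusted p = 1.37e-04), differed by 0.18 in Ly6Clo cells (adjusted p = 0.424) and fell 4.28-fold in PSGL1lo cells (adjusted p = 4.23e-07).

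Ly6c1 was 4.61-fold higher in Ly6Chi than in naive cells (adjusted p = 2.69e-04), 18.5-fold lower in Ly6Clo cells (adjusted p = 7.11e-07) and at least 75.8-fold lower in PSGL1lo cells (adjusted p = 9.64e-09). Ccr7 was 16.1-fold, 3.69-fold and 5.88-fold lower (adjusted p = 2.83e-10, 1.15e-06 and 9.84e-08). Il7r was 3.3-fold lower in Ly6Chi cells (adjusted p = 3.04e-06), differed by -0.17 in Ly6Clo cells (adjusted p = 0.513) and by -0.66 ± 0.20 in PSGL1lo cells (adjusted p = 0.0187, ended without naive replicate 3 at 0.0521 or PSGL1lo replicate 1 at 0.222). Bcl2 was 1.64-fold lower in Ly6Chi cells (adjusted p = 0.0117) and 2.03-fold lower in PSGL1lo cells (adjusted p = 0.00235), and differed by -0.55 in Ly6Clo cells (adjusted p = 0.0528, called without Ly6Clo replicate 3 at 0.00662). The counts were 3965 genes for Ly6Chi (1944 higher, 2021 lower), 3253 for Ly6Clo (1719 higher, 1534 lower) and 4377 for PSGL1lo cells (2156 higher, 2221 lower). Cyclic loess scaling gave 2237 higher and 1936 lower for Ly6Chi, 2048 and 1171 for Ly6Clo, and 2339 and 1616 for PSGL1lo cells. The PSGL1lo count became 2701 without PSGL1lo replicate 1. Non-overlapping groups made up 53.5% and 46.0% of genes for Ly6Chi and Ly6Clo cells (chance gives 10%) and 56.5% for PSGL1lo cells (chance gives 20%).

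With an estimated correlation in place of the preset one, the Th1 effector and Tfh calls held in each of the 3 day 8 comparisons. So did naive and lymph-node homing and other helper lineage genes between Ly6Chi and Ly6Clo cells, and migration genes between Ly6Clo and PSGL1lo cells. Between memory and naive cells the Th1 effector, Tfh, naive and lymph-node homing, inhibitory receptor, migration, other helper lineage, myeloid and NK and CD8 lists held. Th1 effector and naive and lymph-node homing genes held between memory and Ly6Chi cells, and NK and CD8 markers between memory and Ly6Clo cells.

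With fry, a rotation test, in place of camera 12 of the list calls in the 6 main comparisons changed. Calls were gained for migration genes (0.00941) and NK and CD8 markers (0.0107) between Ly6Chi and Ly6Clo cells, and for naive and lymph-node homing (0.00311) and survival genes (0.00101) between Ly6Chi and PSGL1lo cells. T cell receptor response genes were gained between Ly6Clo and PSGL1lo cells (0.044) and between memory and naive cells (0.00256), as were glycolysis genes between memory and naive cells (0.0472). Oxidative phosphorylation genes were lost between memory and naive cells (0.0992) and between memory and Ly6Chi cells (0.196). Between memory and Ly6Clo cells, cell cycle (0.1), inhibitory receptor (0.204) and interferon-stimulated genes (0.173) were lost.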

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

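The tests of the Trbv13-1 levels, of the share of cells without the Smarta receptor and of the dim array were chosen after the result was seen, and a second test of a wrong label was added after the first had come out.

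Probes without a gene symbol, which the comparisons left out, held signal above the naive level: 216 were called higher in memory cells, 391 in Ly6Chi, 319 in PSGL1hi Ly6Clo and 423 in PSGL1lo cells.

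The Trbv13-1 signal lay near the naive level (within 1.5 on the log2 scale) on 9 of the 14 arrays, although its segment encodes the Smarta receptor's beta chain. It was at 14.58 ± 0.07 in Ly6Chi cells against 10.47 ± 0.09 in naive, 10.51 ± 0.18 in PSGL1lo and 10.92 ± 0.68 in memory cells, while Ly6Clo replicate 1 was at 10.46 and Ly6Clo replicates 2 and 3 at 13.13 and 12.83. Lower array signal was argued against by the raw Trbv13-1 signal of Ly6Chi replicate 3, 11.2 times that of naive replicate 1, and a general rise at day 8 by PSGL1lo cells, 0.03 above naive. Cells without the Smarta receptor in the low libraries stay open. The 2 probes of Trbv13-2, another V segment whose signal cannot be parted from Trbv13-1 with certainty, went apart and cannot decide it. The weaker lay lower in Ly6Chi than in naive cells (-2.78 on the log2 scale) and the stronger higher (0.56). The stronger lay at 13.83 to 14.84 on all arrays. On its used probe Foxp3 was likewise lower in Ly6Chi cells than in every other group, and Trgv4 was undetected in Ly6Chi cells. Neither was set as a test. Regulation of Trbv13-1 in PSGL1hi cells of day 8 stays open too, as an untested biological difference between the groups. Ly6Clo replicate 1, also a PSGL1hi array of day 8, was at the naive level.

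PSGL1hi Ly6Clo replicate 1 correlated best with memory replicate 3 (r = 0.9948, against 0.9887 within its group). A memory array under the wrong label was not decided by 2 positions. Replicate 1 lay at 0.801 between Ly6Clo replicates 2 and 3 (0) and memory (1), which restates the correlation, and PSGL1lo arrays lay at 0.742 to 0.775 there. It lay at 0.837 between the other day 8 groups (0) and memory (1), with memory arrays at 0.95 to 1.028, Ly6Clo replicates 2 and 3 at 0.564 and 0.460, and naive arrays at 0.688 to 0.771, of which 2 would have passed the same test. A larger share of cells without the Smarta receptor could account for the correlation, since its other helper lineage genes lay 0.28 above the higher of replicates 2 and 3. Its Trbv13-1 level of 10.46, against 13.13 and 12.83 on replicates 2 and 3 and 10.50 to 11.71 on memory arrays, does not part these 2 explanations. Against a wrong label, its Ly6c1 was 6.06 (memory 10.06 to 11.2) and its NK and CD8 marker mean 0.13 (memory 0.83 to 1.07). Both stay open, as does a difference between the sampled animals, which was not tested.

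PSGL1lo replicate 1 was dim, with a mean signal of 138.9. As the maker of most calls between Ly6Chi and PSGL1lo cells it is argued against by the 2760 genes called without it, 0.68 times the 4038 called with it, of which 2542 were shared. Between Ly6Clo and PSGL1lo cells this stays open, with 1035 genes called without it, 0.48 times the 2141 called with it, of which 959 were shared. No biological explanation was tested.

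The 6 arrays of a comparison make 10 splits, too few for a share under 0.05. For genes, the real split and the highest other gave 1483 and 0 (Ly6Chi against Ly6Clo), 2359 and 2 (memory against naive), 2226 and 0 (memory against Ly6Chi), 22 and 1 (memory against Ly6Clo), 3965 and 0 (Ly6Chi against naive) and 3253 and 0 (Ly6Clo against naive). The real split was the 1 with the most genes in each. For lists, the values were 6 and 9 (6 splits gave as many), 12 and 11 (1 split), 11 and 7 (1 split), and 7 and 10 (4 splits) in the first 4 of these comparisons.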

How the results depend on the processing

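All alternatives were planned. For the 10 genes followed in each of the 9 comparisons, 1541 results under the alternatives stayed on their side of the threshold, 31 lost the call, 18 gained it and 0 turned direction. The direction could not turn under the intensity trend, all probes, the 1.5-fold minimum or the fit of the 2 groups alone, which keep the log2 difference. The series matrix repeats the log2 and quantile setting, so identical results enter these tallies under both names. Beyond single arrays, Il21 was lost between Ly6Chi and Ly6Clo cells with no detection filter (0.103), the replicate block (0.0522) and a fit of the 2 groups alone (0.122), as was Ifng with the last (0.0528). Il7r was lost between memory and naive cells with no detection filter (0.0715), all probes (0.0574) and the block (0.0612), and between PSGL1lo and naive cells with array weights (0.0624) and the 2 groups alone (0.0518). Ccr7 was lost between Ly6Clo and PSGL1lo cells with these last 2 (0.0908 and 0.127). A minimum of 1.5-fold left out Bcl6 and Il7r between memory and naive cells. Calls were gained with array weights for Ly6c1 (0.00455) between memory and naive cells and for Ifng (0.00894), Il7r (0.00366) and Ccr7 (0.00817) between memory and Ly6Clo cells. Bcl2 was gained between memory and naive cells with array weights (0.00546) and in the fit of the 2 groups alone (0.015). Between Ly6Clo and naive cells it was gained with no background correction and with the series matrix (0.0438 in both), an intensity trend (0.0494) and array weights (0.0103). Of the 457 calls of all genes taken by the naming rule or chosen later, 61 were lost without 1 array or another, left out in turn. Of the counts and positions, 253 stayed within 1.5 times the value (counts) or 1 SD of the replicates (positions) and 21 moved further, and the cause was not tested. Array weights (0.30 to 3.25, both PSGL1lo arrays at 0.30) gave 1099 genes for Ly6Clo against PSGL1lo, 5167 for memory against naive (50.4% higher), 4607 for memory against Ly6Chi, 772 for memory against Ly6Clo (378 higher, 394 lower) and 2804 for PSGL1lo against naive. Fits of the 2 groups alone, with fewer arrays behind the spread, gave 821 for Ly6Clo against PSGL1lo and 2902 for PSGL1lo against naive. An estimated correlation left 2 lists for Ly6Chi against PSGL1lo, 3 for Ly6Clo against PSGL1lo, 2 for memory against Ly6Chi and 1 for memory against Ly6Clo, where fry gave 4. Leaving out each array in turn gave ranges of 1077 to 1451 genes (Ly6Chi against Ly6Clo), 2760 to 4824 (Ly6Chi against PSGL1lo), 1035 to 3566 (Ly6Clo against PSGL1lo), 1778 to 2238 (memory against naive), 1587 to 1906 (memory against Ly6Chi), 13 to 379 (memory against Ly6Clo; 161 higher and 218 lower at the highest), 3216 to 3495, 2595 to 3121 and 2701 to 5077 (Ly6Chi, Ly6Clo and PSGL1lo against naive). The lists ran from 5 to 8, 10 to 10, 9 to 11, 11 to 13, 9 to 11 and 6 to 11 in the 6 main comparisons, the memory position from -0.099 to -0.016 and the Ly6Clo position from 0.517 to 0.637. Where a group of 2 kept 1 array, that array was assumed to vary like the other groups. Without PSGL1lo replicate 1, 959 of the 1035 genes called for Ly6Clo against PSGL1lo were shared. Replicate number as a block gave 1411, 3872, 2050, 2331, 2115 and 18 genes in the 6 main comparisons and 3886, 3144 and 4237 against naive cells, with 6, 10, 11, 11, 11 and 8 lists. The block ended the survival list's call between memory and naive cells (0.0545) and added migration genes between memory and Ly6Clo cells (0.0474). Whether the numbers pair the arrays is not settled. Of 26 same-numbered pairs 8 had residuals correlated above 0.1 (-0.24 to 0.30), and 6 of 14 arrays correlated best with their own number. Pairs with different numbers were not set beside these. A BeadChip block was not run, since the chip is not given in the sources used here. With no detection filter 18 lists were tested. The dimmest array, at a mean signal of 138.9, limits what PSGL1lo cells show.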

Other observations

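The lists were also tested for the day 8 populations against naive cells. The genes Erdr1 and Trgv4 and the outlying naive array were chosen after the values were seen. Against naive cells 8 lists were called for Ly6Chi, 12 for Ly6Clo and 10 for PSGL1lo cells, and only a part is named below. With an estimated correlation 4, 6 and 1 lists were called. In Ly6Chi cells Th1 effector genes had 28 of 29 up and 0 down, also adjusted over the list alone (median log2 difference 4.04, or 3.89 with undetected genes at their bounds, adjusted p = 3.47e-25), and naive and lymph-node homing genes 16 of 20 down (19 adjusted over the list alone, median -1.69, adjusted p = 3.06e-12). Migration (median 1.54, or 1.36 at the bounds, adjusted p = 3.05e-10) and inhibitory receptor genes (median 1.31, adjusted p = 7.71e-06) were higher. These 4 calls held with an estimated correlation. Cell cycle genes had 30 of 35 up (median 2.02, adjusted p = 2.66e-19, but adjusted p = 0.073 with an estimated correlation). Tfh genes went both ways, 13 up and 6 down of 28 (adjusted p = 0.156).

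In PSGL1hi Ly6Clo cells 7 of the 12 list calls against naive were Th1 effector (24 of 29 up, median 2.59, or 2.45 at the bounds, adjusted p = 3.08e-19), Tfh (17 of 28 up and 2 down, median 0.73, adjusted p = 9.82e-08), naive and lymph-node homing (15 of 20 down, median -0.83, adjusted p = 3.34e-08), inhibitory receptor (10 of 14 up, median 1.82, adjusted p = 9.82e-08), migration (22 of 32 up and 3 down, median 1.22, or 0.95 at the bounds, adjusted p = 4.31e-10), other helper lineage (11 of 15 up and 1 down, median 2.54, or 2.42 at the bounds, adjusted p = 1.70e-09) and cell cycle genes (29 of 35 up, adjusted p = 9.17e-16, but adjusted p = 0.072 with an estimated correlation), of which all but the last held with an estimated correlation. In PSGL1lo cells Tfh genes had 24 of 28 up and 1 down (median 1.97, adjusted p = 1.75e-15, adjusted p = 0.00743 with an estimated correlation). Against naive cells, PSGL1lo cells had 14 of 35 interferon-stimulated genes down and 2 up (median -0.66, adjusted p = 0.0017, but adjusted p = 0.423 with an estimated correlation) and 19 of 39 oxidative phosphorylation genes down and 1 up (median -0.57, or -0.27 without PSGL1lo replicate 1, adjusted p = 0.00113, but adjusted p = 0.389 with an estimated correlation), while cell cycle genes had 7 up and 2 down of 35 (median 0.02, adjusted p = 0.594). The heat shock list was not called in any of the 9 comparisons.

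Erdr1 was at least 163-fold, at least 147-fold and at least 163-fold higher than naive in Ly6Chi, Ly6Clo and PSGL1lo cells on 1 probe, undetected in naive cells, with its other probe at -0.19 to -0.49. Trgv4, a gamma chain segment of gamma delta T cells, was at 8.73 ± 0.11 in memory, 7.81 ± 0.47 in PSGL1hi Ly6Clo and 6.24 ± 0.84 in naive cells and undetected in Ly6Chi cells. The heat shock gene Hspa1a and the haemoglobin gene Hba-a1 had SDs of 3.50 and 2.78 among the 3 naive arrays, with replicate 2 apart.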
